A study of Mus musculus with 8 samples.

How the data were processed

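RNA was extracted from mouse liver with TRIzol and sequenced from libraries made with a TruSeq RNA kit, per the labels' protocols. Whether strand was used in counting is not given in the sources used here. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Trim Galore 0.4.0, TopHat2 2.0.12, Bowtie2 2.2.3, Cufflinks 2.2.1 and Cuffdiff, whose version was not given. The notes name the builds hg19 and mm10, and the locus coordinates in the tables match mm10. Coordinates printed here are mm10, counted from 1. The authors deposited 3 full tables, 1 per comparison, with pooled FPKM values of the 2 groups compared. The authors also deposited in each table the log2 fold change, the test statistic (a score with no fixed range), the p-value and the q-value of each locus. The other sheets were read only to check that every locus in them has the same q-value in the full table, which held for all of their rows. The per-sample columns left unmapped numbered 0.

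Each full table is scaled on its own. FPKM values of the KO IUB288 group were 1.05 times as high in the treatment table as in the genotype table (median ratio over 4150 loci), and those of the WT IUB288 group 1.08 times (4211 loci). FPKM levels are therefore tested only within a table, and levels set across tables have no test. The difference, the overlap and the slope of KO and WT set results of both treatment tables against each other, from fold changes and calls made within each table. An FPKM of 0 can be a failed estimate in these tables and was not read as absence. Depth per library is not given in the sources used here, so no counting interval was computed.

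Main calls are the authors' own, status OK and q under 0.05, counted by the sign of the log2 fold change, which includes loci listed at 0 in 1 of the groups compared. The smallest p-value in the tables is 5e-05, and the q-values follow from it. The standard error of a log2 fold change was taken as the fold change over the test statistic. At more than 10 FPKM these errors ran from 0.391 to 0.703 (5th to 95th percentile) in the table of the IUB288 effect in WT, so they differ little between genes. They were 1.42 times as large, at the median, as the errors the p-values imply. A gene high in 1 of the 2 mice alone would hardly show in such errors. The difference of the IUB288 effect, KO minus WT, was tested with these errors and Benjamini-Hochberg adjusted. Counts of loci include those without a symbol and those with several.

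Gene lists, 34 in all, covering pathways, liver zonation and cell types, were written before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with cameraPR of limma 3.58.1 in R 4.3.3, at an inter-gene correlation of 0.01, by the statistic (main) and by ranks (alternative). An inter-gene correlation could not be estimated without values per mouse. Where a symbol matched several tested loci, the one with the highest FPKM was used. Adjusted p-values of lists are Benjamini-Hochberg values over the lists tested. Random lists were matched in 20 bins of FPKM, 10000 per list. The main list test called none because of a few very large statistics, so list members were named, by the rule, from the lists called by ranks, a choice made after the data were seen. Genes named outside the rule are marked as chosen after their values were seen.

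The rule named, in each comparison, Nr1h4, Gcgr, Fgf21, Nr0b2, Cyp7a1, Cyp8b1, Abcb11, Pck1, G6pc and Ppargc1a. It also named the 6 largest increases and 6 largest decreases among called loci with 1 symbol, FPKM above 0 in both groups and at least 1 in either. It further named up to 3 called members of each called list, and up to 5 genes in each direction for the difference of KO and WT. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The difference test, the slope, the list tests and the random lists were tested on simulated data with known answers. The alternatives were stricter thresholds, an FPKM minimum of 1, normal p-values from the statistic, centred fold changes, other list settings, other errors, and a pseudocount of 1. Leaving out single mice was not run because no value per mouse was given.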

Results

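Liver RNA was sequenced from 8 mice on a C57Bl/6J background, in 4 groups of 2 mice. WT and KO mice, as the labels name them, received vehicle or IUB288, an agonist of the glucagon receptor. The labels say KO, and the design text names a floxed Fxr gene. Fxr, called Nr1h4 in the tables, encodes the farnesoid X receptor, a nuclear receptor for bile acids. Which exon was targeted, and which recombinase deleted it, is not given in the sources used here, so the tissue of the deletion is not known. The mice had fasted for 2 h. The labels mention high-fat and chow diets without saying which mouse received which, so a difference of diet between groups cannot be ruled out. The authors' deposited tables give 1 pooled FPKM value per group and locus, and no value per mouse, so the spread between mice is known here only through the errors that the authors' test statistics imply. Depth per library is unknown. Each table lists 26682 loci, of which 15164 were tested for the IUB288 effect in WT, 13822 for the IUB288 effect in KO and 13918 for the KO effect under IUB288. Values after ± are implied standard errors on the log2 scale, with 2 mice per group throughout.

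The targeted gene was read first, as a check of the labels. Nr1h4 lies on mm10 chromosome 10 from 89453976 to 89533648. In the authors' deposited table of the KO effect under IUB288 its FPKM was 37.4 in WT and 25.7 in KO, a log2 fold change of -0.54 ± 0.41 with a q-value of 1.00. Under vehicle the authors' deposited tables list 49.3 FPKM in WT and 36.8 in KO, which come from tables scaled separately and carry no test. An FPKM over the whole locus does not show whether an exon is missing, so these values neither establish nor exclude the deletion. Among genes that the farnesoid X receptor acts on, Nr0b2, which encodes the repressor SHP, had a log2 fold change of -0.25 ± 0.40 (q = 1.00) in the authors' deposited table of the KO effect under IUB288. The bile salt export pump gene Abcb11 had -0.40 ± 0.44 (q = 1.00) in the same authors' deposited table.

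The first comparison asked what IUB288 changed in the liver of WT mice. Among 39 genes of xenobiotic metabolism, which include drug-metabolising cytochromes P450, 13 fell and 2 rose. Of 18 stellate cell and fibroblast markers 7 fell and none rose, and of 24 genes of fatty acid and triglyceride synthesis 9 fell and 1 rose. Of the 57 measured genes of the urea cycle and amino acid catabolism 21 rose and 2 fell, with a median log2 fold change of 0.54, and adjusted over the list alone 23 rose and 2 fell. Called by ranks, this list did not stand apart from random lists of like FPKM (adjusted p = 0.215). Over all loci the authors' deposited table called 1117 at q under 0.05, 601 higher and 516 lower. Normal p-values from the test statistic, adjusted likewise, called 219 higher and 173 lower. The largest increases past q of 0.05 among amino acid catabolism genes in the authors' deposited table were Acmsd (3.94 ± 0.50), Cth (2.93 ± 0.47) and Agxt (2.38 ± 0.47), each with q = 0.00163. Acmsd and Cth act in tryptophan and cysteine metabolism, and Agxt in glyoxylate detoxification. Among 20 gluconeogenesis genes 4 rose and 1 fell (7 and 1 adjusted over the list alone), and the list did not stand apart from matched random lists either (adjusted p = 0.74). Got1 (1.89 ± 0.45), the glucose-6-phosphatase gene G6pc (1.55 ± 0.42) and Fbp1 (1.32 ± 0.51) passed in the authors' deposited table, with q = 0.00163, 0.00163 and 0.00653. Pck1, the gene of the cytosolic enzyme that commits oxaloacetate to gluconeogenesis, had 1.12 ± 0.61 with q = 0.0805 in the authors' deposited table and did not pass.

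Of the xenobiotic metabolism genes 17 fell and 3 rose in WT adjusted over the list alone. The authors' deposited table put Cyp2c54 at -6.56 ± 0.65, Cyp2c50 at -6.51 ± 0.57 and Cyp3a11 at -5.49 ± 0.52, each with q = 0.00163. These P450 genes have close paralogs, so reads may be divided between copies. Of the fatty acid and triglyceride synthesis genes 13 fell and 1 rose adjusted over the list alone. Their largest decreases past q of 0.05 in the authors' deposited table were Thrsp (-2.86 ± 0.45), Pparg (-2.72 ± 0.56) and Pnpla3 (-2.60 ± 0.75), with q = 0.00163. Of 17 bile acid and sterol transport genes 6 fell and none rose (7 and none adjusted over the list alone). Among these, the authors' deposited table put the locus of Slco1a1 and Slco1a6 at -3.02 ± 0.41, Abcb1a at -2.37 ± 0.68 and Abcc3 at -2.17 ± 0.57, with q = 0.00163. Abcb1a went from 0.960 to 0.185 FPKM, under 1 in both groups, and its value was -0.73 with a pseudocount of 1. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.74 ± 0.47 on the log2 scale (q = 0.00163) in the authors' deposited table. In that list of bile acid synthesis and conjugation, 3 of 18 genes fell and 1 rose (4 and 2 adjusted over the list alone), and Cyp8b1 had -0.23 ± 0.44 (q = 0.805) in the authors' deposited table.

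Markers of other liver cell types moved as well in WT. Of the stellate cell and fibroblast markers, whose median log2 fold change was -0.95, 12 fell and none rose adjusted over the list alone. The authors' deposited table gave Col1a1 -2.88 ± 0.54, Col3a1 -2.47 ± 0.45 and Col1a2 -2.07 ± 0.50, each with q = 0.00163. Single markers of endothelial cells (Lyve1, -2.47 ± 0.57, 1 of 15) and cholangiocytes (Krt23, -2.57 ± 0.66, 1 of 9) fell in the authors' deposited table, both with q = 0.00163, and each was also the 1 call adjusted over the list alone. The list of 20 clock genes had 8 lower and 4 higher (11 and 6 adjusted over the list alone). Per3 (-4.48 ± 0.59), Bhlhe41 (-3.93 ± 0.86) and Usp2 (-2.62 ± 0.48) fell with q = 0.00163 in the authors' deposited table. Bhlhe41 went from 0.930 to 0.0612 FPKM, under 1 in both groups, and its value was -0.86 with a pseudocount of 1. Arntl (3.34 ± 0.55) and Npas2 (3.32 ± 0.68), named after their values were seen, rose with q = 0.00163 in the authors' deposited table. The DNA replication genes Mcm6 (2.00 ± 0.50, q = 0.00163), Mcm5 (1.76 ± 0.56, q = 0.00163) and Mcm2 (1.52 ± 0.51, q = 0.00543) rose in the authors' deposited table. They were the 3 higher among 18 cell cycle genes, of which 1 fell (4 and 1 adjusted over the list alone). Of 17 macrophage markers 1 rose and 1 fell (2 and 1 adjusted over the list alone). Of 27 acute phase and inflammation genes 10 rose and 3 fell (13 and 3 adjusted over the list alone), beside a median of 0.44 for the macrophage markers, and neither list was called by ranks (adjusted p = 0.154 and 0.05003). On the statistic without the loci whose statistics contradict their p-values, an exclusion made after the data were seen, the acute phase list was called higher (adjusted p = 1.09e-07) and the macrophage list was not called (0.147). Of 15 female-biased liver genes 5 fell and 3 rose in WT (7 and 4 adjusted over the list alone), with a median of -0.93. That list was not called by ranks (adjusted p = 0.241) and was lower than matched random lists (adjusted p = 0.00124).

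The largest called increases and decreases in WT, by the rule for named genes, included genes outside these groups. The authors' deposited table put 3930402G23Rik at 7.41 ± 1.15, Tuba8 at 6.31 ± 0.65, Tmprss7 at 5.88 ± 0.99 (q = 0.00163 each) and Rubie at 5.50 ± 1.77 (q = 0.0267). Their vehicle levels were 0.0598, 0.898, 0.137 and 0.0639 FPKM, and with a pseudocount of 1 their values were 3.39, 5.25, 2.99 and 1.87. Snord89 (6.71 ± 1.01) and Irak1 (6.06 ± 0.29) also rose with q = 0.00163 in the authors' deposited table, and both loci hold annotated small RNA genes, Snord89 itself and, inside Irak1, Mir5132 and Mir718. The largest such decreases in the authors' deposited table were Rgs16 (-7.33 ± 0.59, q = 0.00163), Clec2h (-6.98 ± 1.42, q = 0.00757) and Smpd3 (-5.41 ± 0.86, q = 0.00163), beside the P450 genes. Under IUB288 Rgs16, Clec2h and Smpd3 stood at 0.686, 0.0608 and 0.0571 FPKM, and with the pseudocount their values were -6.04, -3.03 and -1.70. Gcgr, the glucagon receptor gene, had -0.05 ± 0.40 (q = 0.963), Fgf21 -0.12 ± 0.56 (q = 0.936) and Ppargc1a 0.08 ± 0.43 (q = 0.942) in the authors' deposited table. Nr1h4 had -0.29 ± 0.40 (q = 0.68), Nr0b2 -0.07 ± 0.40 (q = 0.955) and Abcb11 -0.52 ± 0.44 (q = 0.402) in the authors' deposited table. Of the 23 genes that the farnesoid X receptor induces, 2 rose and 3 fell (3 and 5 adjusted over the list alone). That list was not called by ranks (adjusted p = 0.387) and was lower than matched random lists (adjusted p = 0.0244).

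The gene list test fixed before the data were examined, limma's cameraPR on the authors' test statistic, called 0 of 31 lists in WT. Its smallest adjusted p was 0.936, and 0 lists had an unadjusted p under 0.05. In WT, 2 loci had statistics above 10 in size beside p-values above 0.05, the largest 771, and such values set the variance against which every list is judged. The planned version by ranks, which such values hardly touch, called 11 lists, 4 higher and 7 lower. They were the respiratory chain (adjusted p = 9.4e-09), stellate cells (6e-07), amino acid catabolism (7.01e-06), xenobiotic metabolism (0.000506), lipid synthesis (0.000696), bile acid transport (0.00158), endothelial cells (0.00698), cholangiocytes (0.0104), cell cycle (0.0313), circadian clock (0.0313) and gluconeogenesis (0.0313). At an inter-gene correlation of 0.05, the calls of gluconeogenesis, circadian clock and cell cycle by ranks were lost (adjusted p = 0.128 each). Of 46 respiratory chain genes 5 rose and none fell (12 and none adjusted over the list alone). Loci above 100 FPKM had a median log2 fold change of 0.43, against 0.03 for all tested loci. Set against 10000 random lists matched on FPKM, the respiratory chain (82.5th percentile, adjusted p = 0.388), amino acid catabolism (91.9th, 0.215), gluconeogenesis (63.0th, 0.74) and cholangiocytes (3.17th, 0.104) no longer stood apart in WT.

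**Figure D1:**
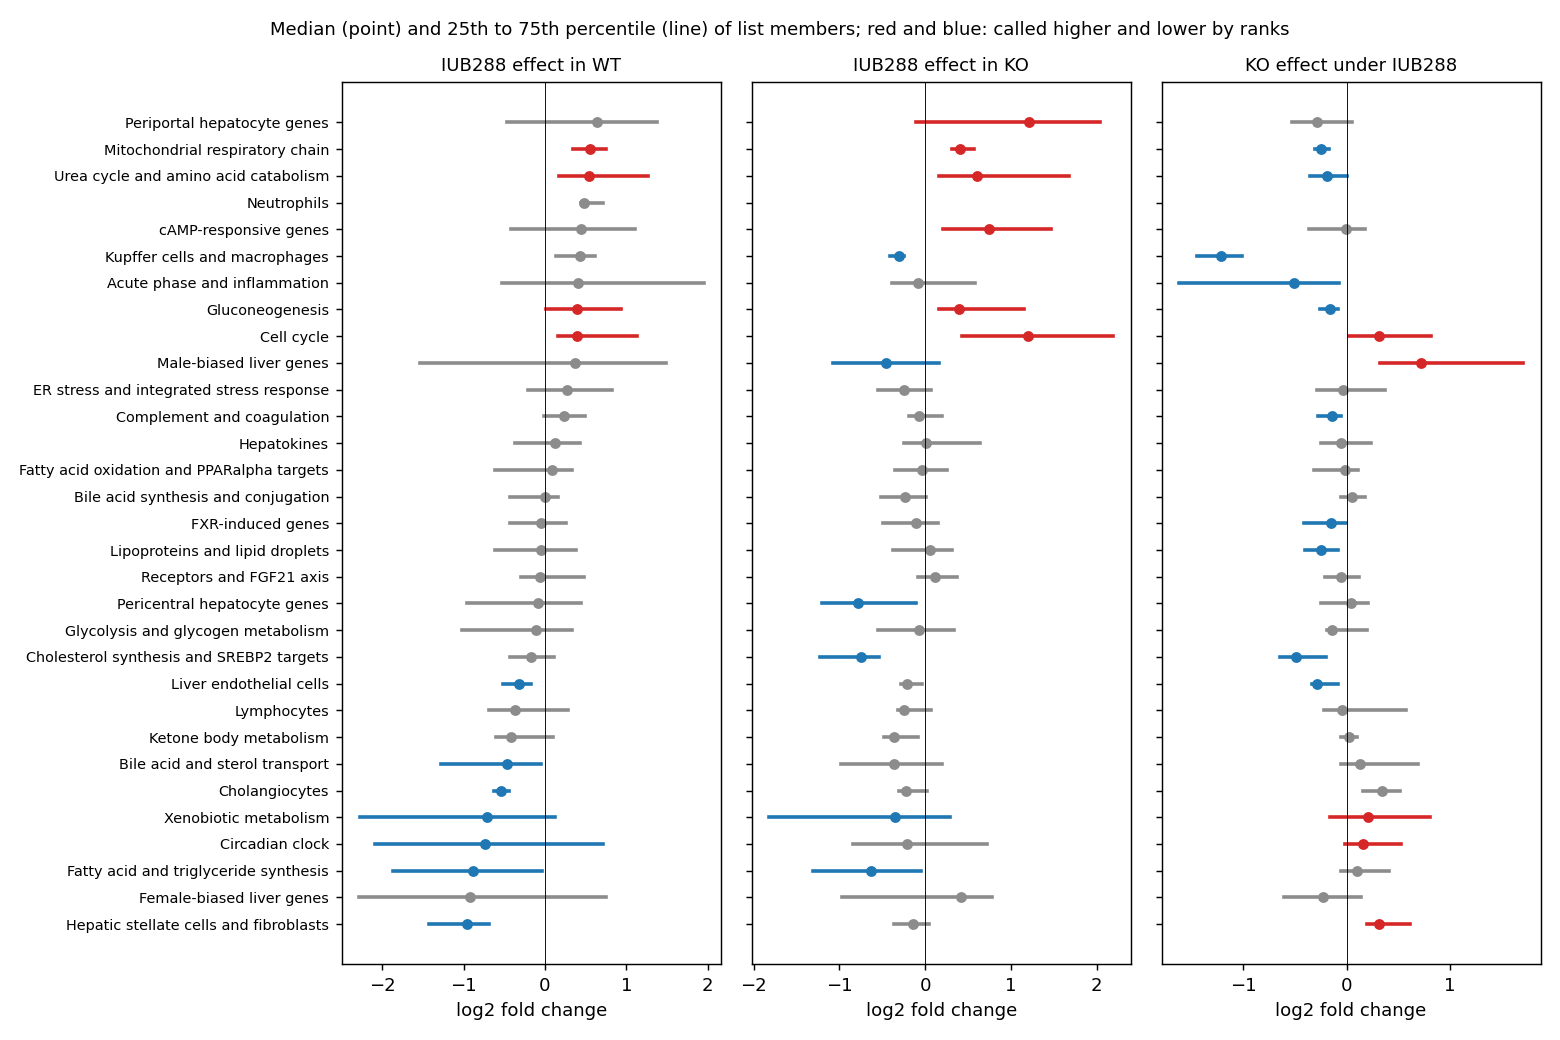
Each point is the median log2 fold change (horizontal axis) of the measured members of a gene list in 1 comparison, and each line runs from the 25th to the 75th percentile of the members. Red and blue lists were called higher and lower by ranks, such as the stellate cell list in WT with a median of -0.95, and grey lists were not called.

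The second comparison asked what IUB288 changed in KO mice. Of 27 cAMP-responsive genes 9 rose and none fell, and of 57 genes of the urea cycle and amino acid catabolism 22 rose and 2 fell. Of 25 cholesterol synthesis genes 10 fell and none rose, and of 23 pericentral hepatocyte genes 9 fell and 2 rose. Over all loci 761 were called in the authors' deposited table, 433 higher and 328 lower, against 174 and 130 by normal p-values from the test statistic. In the authors' deposited table Pck1 rose by 2.49 ± 0.55, Got1 by 2.87 ± 0.41 and Fbp1 by 1.45 ± 0.44 on the log2 scale, with q = 0.00189. Of the 20 gluconeogenesis genes 6 rose and 1 fell (8 and 1 adjusted over the list alone, and adjusted p = 0.105 against matched random lists), and G6pc had 0.74 ± 0.39 (q = 0.0997) in the authors' deposited table. Of the cAMP-responsive genes 14 rose and none fell adjusted over the list alone, and in WT 8 of 28 rose and 3 fell (12 and 5 adjusted over the list alone). In WT that list was not called by ranks (adjusted p = 0.0704) but was higher than matched random lists (99.8th percentile, adjusted p = 0.0172). Without contradictory statistics, left out after the data were seen, it was also called higher in WT (adjusted p = 0.00558). In KO the authors' deposited table put the nuclear receptor gene Nr4a1 at 3.15 ± 0.69 and the kinase gene Sik1 at 2.65 ± 0.39, both with q = 0.00189. Ppargc1a, a coactivator of gluconeogenic genes, rose by 1.15 ± 0.41 (q = 0.00879) in the authors' deposited table. Under vehicle, without a test, Pck1 stood at 880 FPKM in WT and 256 in KO, Got1 at 146 and 58.8, and Ppargc1a at 3.69 and 1.59. G6pc went the other way (50.8 and 92.3). Under IUB288 Pck1 stood at 1920 and 1434, and Ppargc1a at 3.91 and 3.53. None of these genes passed the test of the difference given below. In the amino acid catabolism list 28 rose and 2 fell in KO adjusted over the list alone, among them Cth (3.04 ± 0.46) and Agxt (2.99 ± 0.42) with q = 0.00189 in the authors' deposited table.

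In WT 1 of the 25 cholesterol synthesis genes fell and none rose. The list was not called by ranks there (adjusted p = 0.0827) but was lower than matched random lists (adjusted p = 0.00266). In KO 18 of these genes fell and none rose adjusted over the list alone. Idi1 (-1.67 ± 0.38, q = 0.00189), Sqle (-1.61 ± 0.56, q = 0.0224) and Cyp51 (-1.56 ± 0.37, q = 0.00189) had the largest decreases past q of 0.05 in the authors' deposited table. Lipid synthesis genes fell in 7 of 24 cases with none higher (10 and 1 adjusted over the list alone), the largest past q of 0.05 in the authors' deposited table being Pnpla3 (-3.28 ± 0.59), Thrsp (-2.91 ± 0.40) and Acss2 (-1.83 ± 0.38), with q = 0.00189. Of 39 xenobiotic metabolism genes 12 fell and 2 rose (12 and 3 adjusted over the list alone). The authors' deposited table put Cyp2c54 at -5.49 ± 0.45, Cyp2c50 at -4.84 ± 0.45 and Cyp2c37 at -4.30 ± 0.40, with q = 0.00189. In WT 6 of 23 pericentral genes fell and 3 rose, and 6 of 19 periportal genes rose and 3 fell. Neither list was called by ranks there (adjusted p = 0.379 and 0.154). In KO 9 of the 19 periportal hepatocyte genes rose and none fell. Adjusted over the list alone, 13 pericentral genes fell and 3 rose, and 10 periportal genes rose and 2 fell. Pericentral Cyp2a5 (-2.38 ± 0.38), Cyp2e1 (-1.99 ± 0.61) and Rgn (-1.69 ± 0.42) and periportal Agxt2l1 (3.42 ± 0.44) and Gls2 (2.80 ± 0.48) all had q = 0.00189 in the authors' deposited table. Of 21 male-biased genes 7 fell and 1 rose (the same adjusted over the list alone). Among them the authors' deposited table put Selenbp2 at -4.90 ± 0.46, Hsd3b5 at -2.26 ± 0.39 and Moxd1 at -1.97 ± 0.52, with q = 0.00189. Under vehicle, Selenbp2 and Hsd3b5 stood at 155 and 133 FPKM in KO and at 9.07 and 10.3 in WT, without a test. Of 14 female-biased genes 3 fell and 2 rose with IUB288 in KO (4 and 2 adjusted over the list alone), with a median of 0.41. They were not called by ranks (adjusted p = 0.833) and were higher than matched random lists (adjusted p = 0.0264).

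Other large changes in KO, in the authors' deposited table, were increases of Tuba8 (7.87 ± 0.85, q = 0.00346), 3930402G23Rik (6.47 ± 1.10, q = 0.0111), Cyp2a4 (5.44 ± 0.63), the leptin receptor gene Lepr (5.15 ± 0.57), Gucy2c (4.91 ± 0.88) and Slc13a2 (4.53 ± 0.82), the last 4 with q = 0.00189. Tuba8, 3930402G23Rik, Lepr, Gucy2c and Slc13a2 were under 1 FPKM under vehicle. With a pseudocount of 1 their values were 5.43, 2.53, 2.93, 1.68 and 2.27. The largest called decreases, by the same rule, beyond those already given were Serpina4-ps1 (-6.02 ± 0.85) and Clec2h (-4.23 ± 0.70), with q = 0.00189 in the authors' deposited table. Cyp7a1 fell by 1.56 ± 0.38 (q = 0.00189) in the authors' deposited table, where Cyp8b1 had 0.12 ± 0.40 (q = 0.93), Fgf21 0.65 ± 0.57 (q = 0.507), Gcgr -0.04 ± 0.37 (q = 0.973), Nr0b2 0.27 ± 0.36 (q = 0.743), Abcb11 -0.57 ± 0.40 (q = 0.329) and Nr1h4 -0.44 ± 0.37 (q = 0.454). DNA replication genes Mcm6 (2.72 ± 0.43) and Mcm5 (2.56 ± 0.52) and the cell cycle inhibitor gene Cdkn1a (2.32 ± 0.57) rose with q = 0.00189 in the authors' deposited table, 6 of 14 cell cycle genes rising and none falling, also adjusted over the list alone. Of the 23 genes that the farnesoid X receptor induces, 1 rose and 3 fell, also adjusted over the list alone. That list was called neither by ranks (adjusted p = 0.279) nor against matched random lists (adjusted p = 0.0693). By limma's cameraPR on the statistic, 0 of 30 lists were called in KO (smallest adjusted p 0.998, 0 with an unadjusted p under 0.05). By ranks 12 were called, 6 in each direction, led by the respiratory chain (adjusted p = 1.45e-08), amino acid catabolism (1.12e-06), cholesterol synthesis (1.41e-06) and cAMP-responsive genes (4.23e-05). The others were cell cycle (0.000224), gluconeogenesis (0.000586), lipid synthesis (0.000625), pericentral genes (0.000947), macrophages (0.00362, lower, with none of 16 members called), xenobiotic metabolism (0.0134), periportal genes (0.0156) and male-biased genes (0.0491). Against matched random lists, the gluconeogenesis list alone of these 12 no longer stood apart (96.3th percentile, adjusted p = 0.105). At an inter-gene correlation of 0.05, the calls by ranks of xenobiotic metabolism (adjusted p = 0.13), male-biased genes (0.147) and periportal genes (0.0846) were lost. The respiratory chain had 2 of 46 genes higher and none lower, and loci above 100 FPKM had a median log2 fold change of 0.25.

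The third comparison set KO against WT mice under IUB288, and asked which genes differed between genotypes in treated livers. Such a difference may also be present under vehicle, which was not tested. Of 27 acute phase genes 7 fell and none rose (9 and none adjusted over the list alone), and of 15 macrophage markers 6 fell and none rose (14 and none adjusted over the list alone), with a median log2 fold change of -1.21. Of 22 male-biased genes 6 rose and none fell (8 and none adjusted over the list alone). Over all loci 75 were called in the authors' deposited table, 45 higher and 30 lower in KO, against 16 and 12 by normal p-values from the test statistic. The treated mice are also those of the other comparisons, so these results are not independent of the effects of IUB288 given above. The serum amyloid genes Saa2 (mm10 chromosome 7, 46751833 to 46754314) and Saa1 (chromosome 7, 46740499 to 46742980) lie side by side and are near-identical, so reads may be divided between them. Saa2 fell in the authors' deposited table from 748 to 8.6 FPKM (-6.44 ± 0.58) and Saa1 from 982 to 19.1 FPKM (-5.69 ± 0.55), with q = 0.0118. The lipocalin gene Lcn2 (chromosome 2, 32384632 to 32388065) had -4.72 ± 0.57 and the metallothionein gene Mt2 -4.05 ± 0.50, with q = 0.0118, in the authors' deposited table. Unlike Saa1, Saa2 and Lcn2, Mt2 was not among the loci whose response to IUB288 differed between genotypes. Among the macrophage markers, Marco (-2.10 ± 0.52), C1qa (-1.49 ± 0.42) and C1qb (-1.49 ± 0.43) had the largest decreases among the called, with q = 0.0118 in the authors' deposited table. The largest increases past q of 0.05 among male-biased genes in the authors' deposited table were Cyp4a12b (3.79 ± 0.72), the Slco1a1 and Slco1a6 locus (3.54 ± 0.46) and Cyp4a12a (2.63 ± 0.45), with q = 0.0118. The authors' deposited values under vehicle, scaled separately and without a test, were 83.2 FPKM in WT and 144 in KO for Cyp4a12a. They were 5.68 and 6.92 for Cyp4a12b. For Hsd3b5 they were 10.3 and 133, and for Elovl3 33.0 and 93.6, both chosen after their values were seen.

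Among the remaining calls under IUB288, the authors' deposited table put Cyp3a11 at 3.74 ± 0.48, Cyp2c50 at 2.40 ± 0.55, Cyp2c29 at 1.77 ± 0.45, H2-Bl at 3.96 ± 0.77 and Gas2l3 at 2.88 ± 0.61, with q = 0.0118. Mcm6 had 1.27 ± 0.42 (q = 0.0282), and Akr1b7, on the list of genes that the farnesoid X receptor induces, had -2.49 ± 0.63 (q = 0.0118), in the authors' deposited table. It was the 1 called gene of the 23 on that list, also adjusted over the list alone. By ranks the list was called lower (adjusted p = 0.0448), and this call was lost at an inter-gene correlation of 0.05 (adjusted p = 0.149) and against matched random lists (adjusted p = 0.929). Snord89 (-6.13 ± 0.93) and Irak1 (-6.00 ± 0.29) also had q = 0.0118 in the authors' deposited table, with the small RNA genes noted above. None of Gcgr, Fgf21, Cyp7a1, Cyp8b1, Pck1, G6pc or Ppargc1a passed, with log2 fold changes of -0.11, 0.30, 0.73, 0.72, -0.39, 0.08 and -0.12 in the authors' deposited table and q-values from 0.787 up. By limma's cameraPR on the statistic, 0 of 30 lists were called (smallest adjusted p 1.00, 0 with an unadjusted p under 0.05). By ranks 15 were called, led by macrophages (adjusted p = 4.05e-07, lower), male-biased genes (4.05e-07, higher), the respiratory chain (2.01e-06, lower), cholesterol synthesis (3.79e-06, lower) and acute phase (6.53e-05, lower). No respiratory chain or cholesterol synthesis gene passed in this comparison. Beside the macrophage and acute phase lists, stellate cell and fibroblast markers were called higher by ranks (adjusted p = 0.00192), with a median of 0.31 and none of 17 past the threshold. That call was kept at an inter-gene correlation of 0.05 (adjusted p = 0.0205) and against matched random lists (adjusted p = 0.00514). Endothelial markers were called lower by ranks (adjusted p = 0.0248), with a median of -0.29 and none of 15 past the threshold, and were not called at a correlation of 0.05 (adjusted p = 0.0944), while they stood apart from matched random lists (adjusted p = 0.006). Of the 15 lists, 9 were also called in the same direction against matched random lists, and the respiratory chain was not (9.89th percentile, adjusted p = 0.303). With an inter-gene correlation of 0.05, 6 of them remained called by ranks. Loci above 100 FPKM had a median log2 fold change of -0.20.

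**Figure D2:**
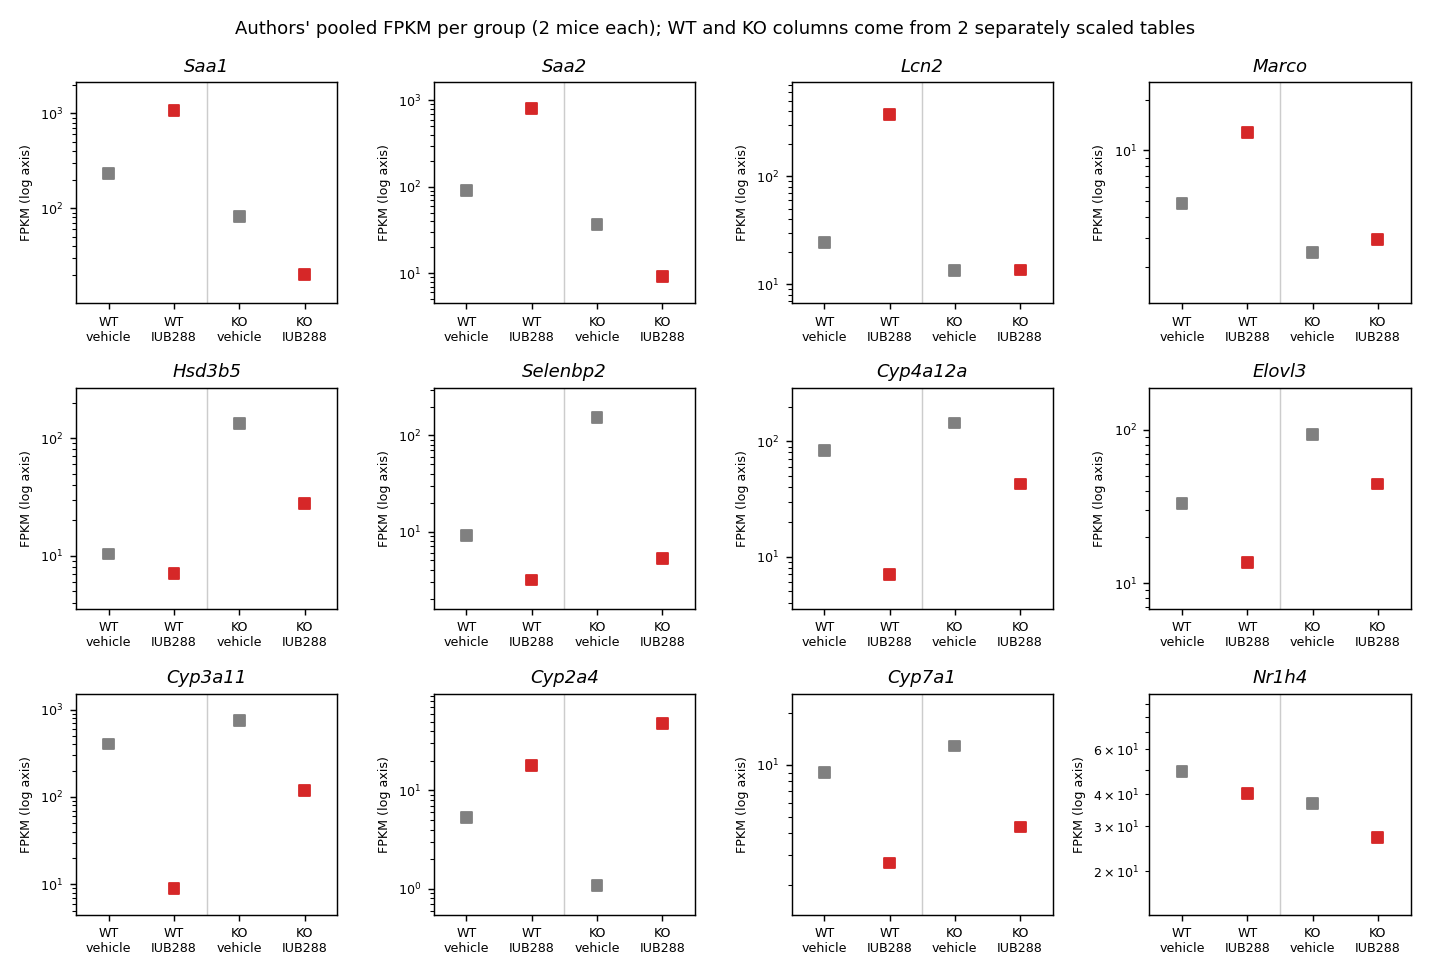
Each square is the authors' pooled FPKM of 1 group of 2 mice on a log axis, without an error bar because no value per mouse was given. Saa1 stood at 1062 FPKM in WT under IUB288 and at 20.1 in KO under IUB288, and WT and KO columns come from separately scaled tables.

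Whether the response to IUB288 differed between genotypes was tested gene by gene as the difference of the log2 fold changes, KO minus WT, over 13521 loci. At adjusted p under 0.05, 14 loci differed, 8 in the positive and 6 in the negative direction, by a two-sided normal test on implied errors, which is not an exact test. At an unadjusted p under 0.05 there were 146, fewer than that threshold passes when no locus differs. The implied errors are therefore larger than the spread of the differences at most loci. Saa2 differed by -5.17 (adjusted p = 1.58e-09), Saa1 by -4.21 (1.08e-06) and Lcn2 by -3.91 (5.93e-05). In the authors' deposited tables these genes had log2 fold changes of 3.16, 2.18 and 3.91 with IUB288 in WT and -2.01, -2.03 and 0.01 in KO. Cyp2a4 differed by 3.68 (adjusted p = 0.00792), Cyp4a12b by 3.48 (0.0325), Rgs16 by 3.34 (0.0268), Egr1 by 3.21 (0.00527), Cyp26b1 by 3.002 (0.0325), Derl3 by -3.52 (0.0325) and Irak1 by -6.06 (2.79e-34). The authors' deposited values under vehicle were 110 FPKM in WT and 22.2 in KO for Rgs16, 8.93 and 2.00 for Egr1, and 2.84 and 0.530 for Cyp26b1. For these genes the KO effect under IUB288 did not pass (authors' q from 0.265 up). Cyp4a12b (5.68 and 6.92) and Irak1 (14.4 and 14.7) stood closer together under vehicle. The power of the difference test was low. In simulated data with the same errors, over 13509 loci, it recovered 68% of differences of 3 and 11% of differences of 1.5 on the log2 scale, with 7 false calls, so the loci that did not pass cannot be called alike. The simulation took the implied errors as true, so its false calls do not show whether those errors are right with 2 mice per group. As the count of 146 points to errors that are too large, its recovery and false calls need not hold for these data. With errors implied by the p-values instead, 11 loci passed, of which 6 were among the 14. Since no p-value is below 5e-05, such errors grow with the fold change of strongly changed genes, so a call lost in this way says nothing on its own of Irak1, Lcn2 and others at that floor.

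Of 13585 loci tested in both genotypes, 302 were called higher in both, against 18.6 for independent lists, and 205 were called lower in both, against 11.1. One-sided Fisher's exact tests gave log10 p-values of -341 and -233, and the groups shared no mice. Called in both with opposite signs were 4 loci, Saa1, Saa2, Zbtb16 and, named after its values were seen, B020031M17Rik, which the authors' deposited tables list at 0 in a group of each. Loci are not independent of each other, so these tests describe the overlap across loci. The size of the KO response relative to WT depended on the estimator. The error-weighted slope fixed in advance was 1.38, and 0.835 without the loci whose statistics contradict their p-values, an exclusion made after the data were seen. The mt-Tl2 and mt-Ts2 locus, with an implied error of the difference of 0.00318, weighs far more in the first slope than a usual locus. Its log2 fold changes were 2.26 in WT and 3.14 in KO, so the 1.38 is not read as the size of the KO response. The median KO to WT ratio was 0.69 over loci called in WT and 1.02 over loci called in KO. Choosing loci by their call in WT lowers the first ratio, and choosing them by their call in KO raises the second. Neither is therefore read as the size of the KO response.

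**Figure D3:**
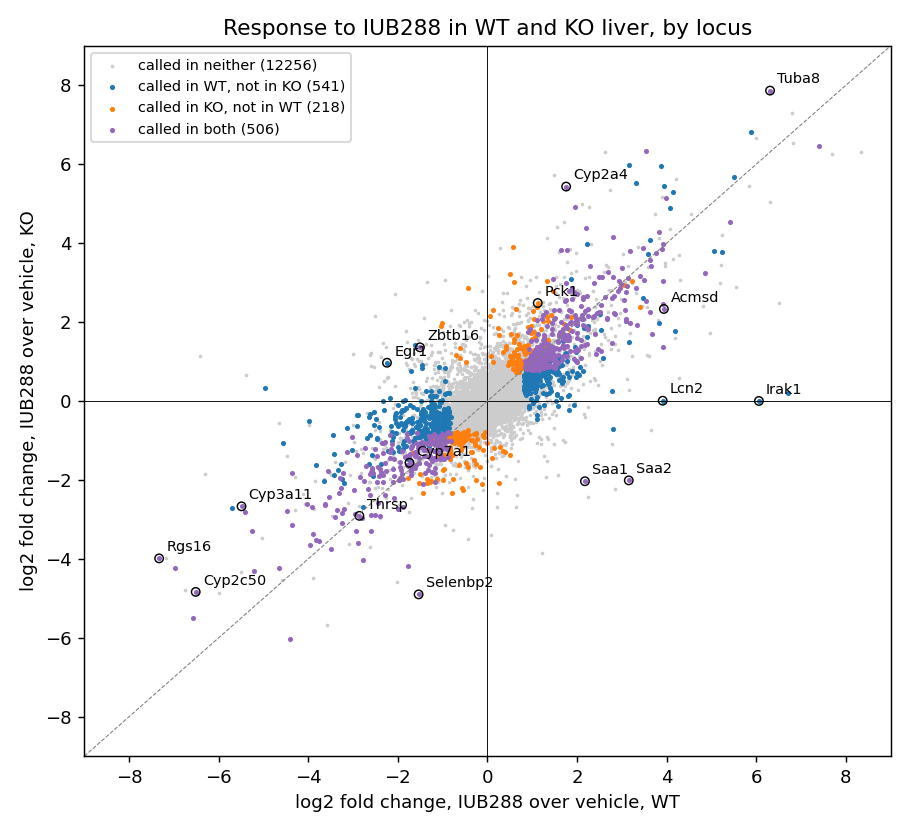
Each point is a locus, with the log2 fold change of IUB288 over vehicle in WT on the horizontal axis and in KO on the vertical axis, and the dashed line marks equal responses. Of the 302 loci called higher in both and the 205 called lower in both, those with a finite fold change lie at the upper right and the lower left, while Saa1 (2.18 in WT, -2.03 in KO) and Selenbp2 (-1.53 in WT, -4.90 in KO) lie away from the line.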

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

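The tests of macrophage RNA, of scaling, of a single mouse and of small RNAs were chosen after the results were seen, and those of Xist and of growth hormone genes before.

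The IUB288 log2 fold change differed between KO and WT, by the test of the difference itself, at 14 loci. Values are KO minus WT, and were -6.06 for Irak1, -5.17 for Saa2, -4.21 for Saa1, -3.91 for Lcn2, -3.52 for Derl3 and -3.36 for Selenbp2. Positive differences were 0.873 for the mt-Tl2 and mt-Ts2 locus, 2.82 for Cyp3a11, 2.87 for Zbtb16, 3.002 for Cyp26b1, 3.21 for Egr1, 3.34 for Rgs16, 3.48 for Cyp4a12b and 3.68 for Cyp2a4. The error implied for the mt-Tl2 and mt-Ts2 locus comes from statistics of 771 and 2551 beside p-values of 0.47 and 0.441, so its call rests on an error that the p-values contradict. The adjusted p-values of Zbtb16 and Cyp3a11 were 0.0316 and 0.0435. Selenbp2 had 9.07 FPKM in WT and 155 in KO under vehicle, and Zbtb16 11.9 and 1.97, in the authors' deposited tables, which were scaled separately. Under IUB288 the same tables list Zbtb16 at 4.18 FPKM in WT and 5.05 in KO. A difference in the response can therefore start from a difference under vehicle, which no table used here tests.

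Acute phase genes rose with IUB288 in WT, 10 of 27 with 3 lower, and the list as a whole was not called by ranks there (adjusted p = 0.154) or against random lists (0.252), but was called higher on the statistic without contradictory values, left out after the data were seen (1.09e-07). More macrophage RNA in the WT IUB288 livers stays open: the macrophage list had a median log2 fold change of 0.44, lower by 2.04 (-2.04) than the 10 acute phase members called higher, which were chosen for being high, while the whole acute phase list had a median of 0.41. In the authors' deposited table the most abundant markers under IUB288, C1qb, C1qc and Cd5l, went from 38.3, 32.2 and 28.3 FPKM to 56.7, 51.3 and 50.2 FPKM in WT, and Marco, the 1 marker called higher, from 4.78 to 12.8 FPKM. A shift in scaling in the WT table would move every gene alike if it were 1 factor, while the called acute phase members ran from -1.37 to 3.91, a range of 5.29 with an error of 0.655. That range was taken over members chosen for being called, and its criterion was written after the counts were seen, so the test cannot decide on scaling. In WT, loci above 100 FPKM had a median log2 fold change of 0.43 and those at 1 to 10 FPKM -0.05, so a shift that depends on level stays open. One WT mouse with inflammation could account for the rises seen in WT alone, as could diet, which was not tested. A single mouse is not excluded because the errors span only a ratio of 1.798 from the 5th to the 95th percentile and are hardly specific to a gene. Mt1 and Mt2, which are among the 10, rose with IUB288 in KO as well, so a WT mouse would not account for that part.

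Male-biased genes changed with IUB288, 8 higher and 6 lower of 21 in WT, where the list was called neither by ranks (adjusted p = 0.577) nor against random lists (0.434), and 1 higher and 7 lower of 21 in KO. Female mice in a group are argued against, since Xist, which the authors did not test, was at most 0.0172 FPKM in any group of the authors' deposited tables. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a median log2 fold change of -0.44 with IUB288 over WT and KO, the direction that female mice would give. A shift in scaling of all genes by 1 factor would move every gene alike, while the called members in WT ran from -3.98 to 2.68, a range of 6.66 with an error of 0.79. That range was again taken over members chosen for being called, and its criterion was written after the counts were seen, so the test cannot decide on scaling here either. Lower growth hormone signalling is a hypothesis that the test left open. The median log2 fold change of Igf1, Igfals, Socs2, Cish and Ghr was -0.43 in WT and -0.58 in KO, so the bound of -0.5 set in advance was met in KO and not in WT, and female-biased genes had medians of -0.93 in WT and 0.41 in KO.

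Very large statistics stood beside p-values that did not pass at 10 loci over the 3 tables, up to 16333 in size. Of these loci, 100% held an annotated small RNA gene or were under 200 bases long, against 12.8% of all 15351 tested loci. The share was thus higher at these loci. A candidate explanation is short RNAs inside the loci, whose FPKM is unstable, but a higher share alone does not show that cause. The share among all loci also lay above the 10% bound for that reading, itself written after the results were seen, so the test left the cause open.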

How the results depend on the processing

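The ranks with an inter-gene correlation of 0.05 and the exclusion of contradictory statistics (above 10 in size beside a p-value above 0.05) were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the tables hold no values per mouse and the mouse numbers are not shared between groups. Leaving out each mouse was not run for the same reason. The causes were not tested unless stated.

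In the order IUB288 effect in WT (higher, lower), in KO (higher, lower) and KO effect under IUB288 (higher, lower), q under 0.01 left 345, 297, 284, 205, 0 and 0 loci. The zeros follow from construction, since the smallest q-value in that table is 0.0118. Normal p-values from the statistic gave 219, 173, 174, 130, 16 and 12 loci, and centred fold changes with the same p-values 200, 181, 175, 130, 16 and 12. Counts with an FPKM minimum of 1, or with an absolute log2 fold change of at least 1, stayed within 1.5 times of the main ones. The overlap of WT and KO calls, 507 in all, was 312 at q under 0.01.

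The gene list counts, 0 in each comparison as fixed in advance, depended on the setting, in the order WT, KO and genotype, though an inter-gene correlation of 0.05 or an FPKM minimum of 1 on the statistic also gave 0 in each. Tests on log2 fold changes called 9, 11 and 5 lists, by ranks 11, 12 and 15, against random matched lists 16, 17 and 13, by ranks with an inter-gene correlation of 0.05 they called 8, 9 and 6, and without the contradictory statistics 15, 14 and 14. Of the lists called by ranks, 7, 11 and 9 were also called in the same direction against random lists. In simulated data with 3 absurd statistics added, the main test likewise missed a raised list that the rank test found.

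The count of loci whose response differed was 14 as fixed and from 11 to 14 otherwise. With errors implied by p, which the smallest p-value inflates for large fold changes, it was 11, of which 6 were shared, and without contradictory statistics 13, all shared. The slope of KO on WT was 1.38 as fixed, 1.38 with an FPKM minimum of 1, and 0.835 without contradictory statistics. The FPKM minimum is no check of the slope, since it keeps the mt-Tl2 and mt-Ts2 locus, which reached 13937 FPKM. The median ratio was 0.69 over loci called in WT and 1.02 over loci called in KO, each biased by the choice of its loci. Of 144 values of named genes, all 144 moved by less than the implied error with centred fold changes, a shift of at most 0.033 that could hardly move them, and 44 moved by more with a pseudocount of 1 added to FPKM, none of them changing the sign of a called value. Among the 44 were, in WT, Smpd3 from -5.41 to -1.70, Bhlhe41 from -3.93 to -0.86 and Pnpla3 from -2.60 to -0.87.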

Other observations

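Of 20 clock genes 4 rose and 5 fell with IUB288 in KO (7 and 5 adjusted over the list alone), and the list was not called by ranks there (adjusted p = 0.538), while its call in WT was lost at an inter-gene correlation of 0.05 (adjusted p = 0.128). The next 4 of its genes were chosen after their values were seen. In the authors' deposited tables Arntl had a log2 fold change of 3.34 ± 0.55 in WT and 1.93 ± 0.44 in KO, and Npas2 3.32 ± 0.68 and 2.87 ± 0.67. Per3 had -4.48 ± 0.59 and -2.78 ± 0.45 there, and Per2 -1.90 ± 0.55 and -1.27 ± 0.47, with q-values from 0.00163 to 0.00493 over these 8 values in the authors' deposited tables. The time of day of each collection was not used here.

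The metallothionein genes Mt1 and Mt2 are both members of the acute phase list. They were also chosen here after their values were seen, although the rule named Mt2 in the KO effect under IUB288. They do not stand for the whole list. For the IUB288 effect the authors' deposited tables put Mt1 at 3.11 ± 0.44 in WT and 2.91 ± 0.43 in KO, and Mt2 at 3.91 ± 0.48 and 3.98 ± 0.68, with q = 0.00163 in WT and 0.00189 in KO for both. Under IUB288 the authors' deposited table of the KO effect lists Mt1 at 1464 FPKM in WT and 126 in KO (-3.53 ± 0.44), and Mt2 at 832 and 50.2 (-4.05 ± 0.50), with q = 0.0118 for both. As both genes rose by like amounts in WT and KO, a gap of like size stood under vehicle, which was not tested. The gap under IUB288 is therefore not read as a difference in response. Under IUB288, 2 of the 3 measured erythroid genes were higher in KO, Hba-a1 (1.39 ± 0.44, q = 0.0118) and Hbb-b1 (1.31 ± 0.46, q = 0.0208), in the authors' deposited table, a list too small to be tested.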
